A study of Oryza sativa with 23 samples.

How the data were processed

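Total RNA was taken from whole roots and L2 leaves of the rice varieties Hacha and Lachit, with the RNeasy plant mini kit, and libraries were built with version 2 of Illumina's TruSeq RNA kit, per the labels' protocols. That kit does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. Libraries were assigned to 8 groups of variety, tissue and treatment from their titles, and each file was tied to its library by the record of the series, not by its name. The titles give each library a running number of its own, so replicates were numbered within a group and no pairing was assumed. The labels name no sequencing batch.

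Each library came as a table with 1 line per transcript, holding an effective length, an estimated count and a TPM value (transcript level relative to all transcripts of the library). The authors' estimated counts come from kallisto, which the submitters' processing notes name together with bcl2fastq and the build IRGSP-1.0; versions, the transcript set and the settings of kallisto are not given in the sources used here. Estimated counts are not normalized, and reads that match several transcripts were shared out between them by the program, so genes with near-identical copies carry an uncertainty that the files do not show. The deposited TPM values are scaled by the authors' processing to transcript length and to the same total in each library, per the file headers and the values. A further table of TPM values over all libraries was not used.

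The 42346 transcripts were summed to 35679 genes by their identifiers, and the sums of estimated counts were rounded to whole numbers. Totals ran from 16659607 to 33386840 counts per library. Counts of 0 over a group were given a floor of 3 counts over that group. Folds against such a group are lower bounds from that floor, and ratios against 1 to 3 reads have 95% exact binomial intervals; both cover counting error only, since PCR copies cannot be told apart without molecular identifiers. No 2 replicates agreed within sampling noise: the chi-square per gene between libraries of a group lay between 8.1 and 298. All were kept as separate samples.

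Gene names were sought in a RefSeq table of the assembly ASM3414082v1, which matched 1 of the files' gene identifiers and gave no symbol for it. Genes are therefore printed by identifier alone, and their proteins are not named. The chromosome given for a gene is the one its identifier carries by the naming convention of this annotation, and positions are not given. For the same reason the 27 gene lists fixed before the data were examined could not be filled, and the 4 list tests planned on them were not run.

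The main test was edgeR's quasi-likelihood F test with robust dispersion (edgeR 4.0.16, R 4.3.3), fitted separately for root and leaf over the 4 groups of each, after filterByExpr and TMM scaling. This left 27479 genes in root and 25505 in leaf. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 10 contrasts were excess iron against control in each variety and organ, the difference of these responses between the varieties in each organ, and Lachit against Hacha in each organ and solution. CPM values are counts scaled to library size by the TMM factors. The named genes are the 2 with the largest rise and the 2 with the largest fall of each contrast, among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups (overlap was not considered for the difference of responses). The tests, groups, alternatives and this rule were set before the data were examined, except that the rule first asked for more genes with descriptive names; this was reduced to identifiers once the reference had been read and before any fold change was computed.

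TMM centred the medians of the log2 fold changes over all tested genes within 0.05 of 0 for the treatment contrasts. With library totals alone the medians were -0.31 in Hacha root, -0.1 in Lachit root, -0.08 in Hacha leaf and 0.29 in Lachit leaf, so changes are relative to the typical gene and not to the amount of RNA in the tissue.

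Alternatives were size factors as in DESeq2 within edgeR, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared or of both tissues, offsets from mean effective transcript length, a minimum log2 fold change of 1, limma 3.58.1 on log2(TPM + 1), and leaving out each library in turn. A fit without 2 leaf libraries that stood apart and a scaling by library totals were added after the data were seen. Where Hacha root under excess iron was reduced to 1 library, that library was assumed to vary like the other groups.

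The numbers expected for independent lists are the product of the 2 lists' sizes over the genes tested in both. The treatment comparisons of the varieties and of the organs share no libraries. Response scores project a library's difference from the other control libraries of its group on the log2 fold changes of the genes called in the other variety. Positions along chromosomes were taken from the order of identifiers, with 1000 permutations within chromosomes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3).

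The tests were run first on simulated counts with the real library sizes and dispersions. The groups of a contrast were given their average level for each gene, and 200 genes were then changed. Far more genes were called in the data, where the Benjamini-Hochberg threshold is therefore less strict. The shares recovered hold for this setting and may be higher in the data. In Hacha root 70% of 2-fold and 92% of 4-fold changes were recovered among 27479 genes, and in Lachit root 78% and 98%. In Hacha leaf 12% of 2-fold and 73% of 4-fold changes were recovered among 25505 genes, and in Lachit leaf 19% and 84%. For the difference of responses the shares were 30% and 92% in root and 2% and 37% in leaf. For the varieties in control root they were 79% and 98%, in control leaf 16% and 80%, in excess-iron root 78% and 98%, and in excess-iron leaf 21% and 84%. Between 1 and 11 unchanged genes were called in each.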

Results

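Gene expression was measured by RNA sequencing in whole roots and L2 leaves of 11-day-old rice plants (Oryza sativa) of the varieties Hacha and Lachit, which the series describes as contrasting. For the last 2 days the plants stood either in the control nutrient solution, with 50 µM Fe as an EDTA chelate at pH 6.2, or in the same solution with iron sulfate added to 15 mM and a pH of 5.2, called excess iron here. Acidity and sulfate changed together with iron, so each treatment comparison covers these changes jointly. The 23 libraries form 8 groups of variety, tissue and treatment, with 3 libraries in each group except excess-iron root of Hacha, which had 2. The series describes triplicates, and no further replicate of that group was analysed here. Each library held between 16659607 and 33386840 estimated counts over 35679 genes. The labels do not say whether the replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The comparisons ask how each variety responded to excess iron in each organ, whether the responses differed between the varieties, and how the varieties differed in each solution.

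In leaves, the most abundant genes took a smaller share of the reads under excess iron. The 20 most abundant genes held 14.2% ± 1.8 (SD, n = 3) of the counts in control leaves of Hacha and 14.6% ± 0.6 (n = 3) in those of Lachit. Under excess iron these shares were 7.93% ± 1.7 (n = 3) and 7.7% ± 0.34 (n = 3), with every excess-iron library at or below 9.81% and every control at or above 12.2%. In roots the group means lay between 6.6% and 8.36% in all 4 groups. The first principal component of the log2 CPM (read counts scaled to library size) separated control from excess-iron libraries of each variety and held 51.8% of the variance in root and 55.7% in leaf. The second separated the varieties and held 33.2% and 26.8%. The common biological coefficient of variation was 17.7% in root and 33.6% in leaf. The lowest correlation between replicates was 0.973 to 0.977 in the root groups, 0.98 in control leaves of Lachit and 0.902 to 0.949 in the other leaf groups.

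In roots of Hacha, excess iron changed 17128 of the 27479 tested genes, of which 8145 rose and 8983 fell. Large falls were more frequent than large rises: 2362 of the called genes fell at least 8-fold and 1017 rose at least 8-fold. The steepest rises were in OS04G0538300 on chromosome 4, with no reads in the 3 control libraries and 43.5 ± 0.63 CPM (SD, n = 2) under excess iron, at least 1110-fold higher, and in OS01G0893700 on chromosome 1. The latter had 2 reads in control and 1383 under excess iron, a ratio of 1530 with a 95% counting interval of 423 to 12600. The steepest falls were in OS11G0484450, from 62.8 ± 19 CPM (n = 3) to no reads, at least 713-fold lower, and in OS05G0215066, from 43.4 ± 5.4 CPM (n = 3) to no reads, at least 499-fold lower. For these 4 genes the adjusted p lay between 7.16e-08 and 1.43e-06 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Every excess-iron library lay beyond every control library. The rule for naming genes required this here and in the other contrasts, apart from the difference of responses. On log2(TPM + 1) values, limma called 5563 genes higher and 12320 lower. With a minimum of 1 on the log2 scale, 10851 genes were called.

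In roots of Lachit, excess iron changed 16127 genes, 8087 upward and 8040 downward. Of these, 891 rose and 1406 fell at least 8-fold. OS07G0531200 on chromosome 7 had no reads in control roots of Lachit and reached 12.8 ± 3.3 CPM (SD, n = 3), at least 327-fold higher. OS04G0660900 on chromosome 4 rose from 0.0911 ± 0.062 to 224 ± 7.6 CPM (n = 3 each), a log2 fold change of 11.22 (SE 0.7, adjusted p = 5.48e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with all 3 excess-iron libraries above all 3 controls. The same gene stood at 0.819 ± 1 CPM in control and 455 ± 120 CPM in excess-iron roots of Hacha. OS07G0116050, also on chromosome 7, fell from 10.3 ± 2.2 CPM to no reads, at least 273-fold lower, and had no reads in roots of Hacha in either solution. OS04G0554500 fell from 2737 reads to 1, a ratio of 2740 with a counting interval of 492 to 108000. With a minimum of 1 on the log2 scale, 9049 genes were called.

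The root responses of the varieties went the same way for most genes. Of the 12766 genes called in both varieties, 5932 rose in both and 6422 fell in both, against 2397 and 2628 for independent lists, and 412 moved in opposite directions, against 5027. Across the tested genes, which are not independent replicates, the log2 fold changes of the varieties had a Pearson r of 0.76. The response was smaller in Lachit: over the 12354 genes that moved the same way, the median ratio of the Lachit to the Hacha log2 fold change was 0.77 (jackknife SE 0.091 over libraries), and 72.8% changed more in Hacha. Only genes called in both varieties enter this ratio. With 2 excess-iron libraries, Hacha may need larger changes for a call, which would lower the ratio. Leaving out 1 library in turn gave ratios of 0.72 to 0.82. The test of the difference itself called 5332 genes, 3415 with a higher and 1917 with a lower log2 fold change in Lachit. Among them, 2220 changed in the same direction in both varieties and more in Hacha, 384 in the same direction and more in Lachit, and 412 in opposite directions. A further 620 rose and 822 fell past the threshold in Hacha alone, and 546 rose and 301 fell in Lachit alone.

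The single genes named for the difference of the root responses were of different kinds. OS11G0484450, without a read in excess-iron roots of Hacha, kept 30.2 ± 11 CPM (SD, n = 3) in those of Lachit, against 87.6 ± 8.6 CPM (n = 3) in the Lachit controls. OS05G0215066, at 43.4 CPM in control roots of Hacha, had at most 4 reads in either group of Lachit roots, too few to measure a response there. In the other direction, OS11G0183150 went from 0.715 ± 0.28 to 13.9 ± 2.1 CPM in Hacha and from 0.359 ± 0.14 CPM to no reads in Lachit, and OS12G0207600 from 0.197 ± 0.043 to 10.6 ± 6.3 CPM in Hacha and from 0.181 ± 0.16 to 0.0645 ± 0.11 CPM in Lachit. The Lachit values of OS12G0207600 rest on 15 reads in control and 6 under excess iron. The count of genes with a differing root response fell to 3434 without Hacha excess-iron library 1, to 2801 without library 2 and to 2057 when both tissues shared a fit. On log2(TPM + 1) limma called 5555 higher and 1567 lower in Lachit.

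**Figure D1:**
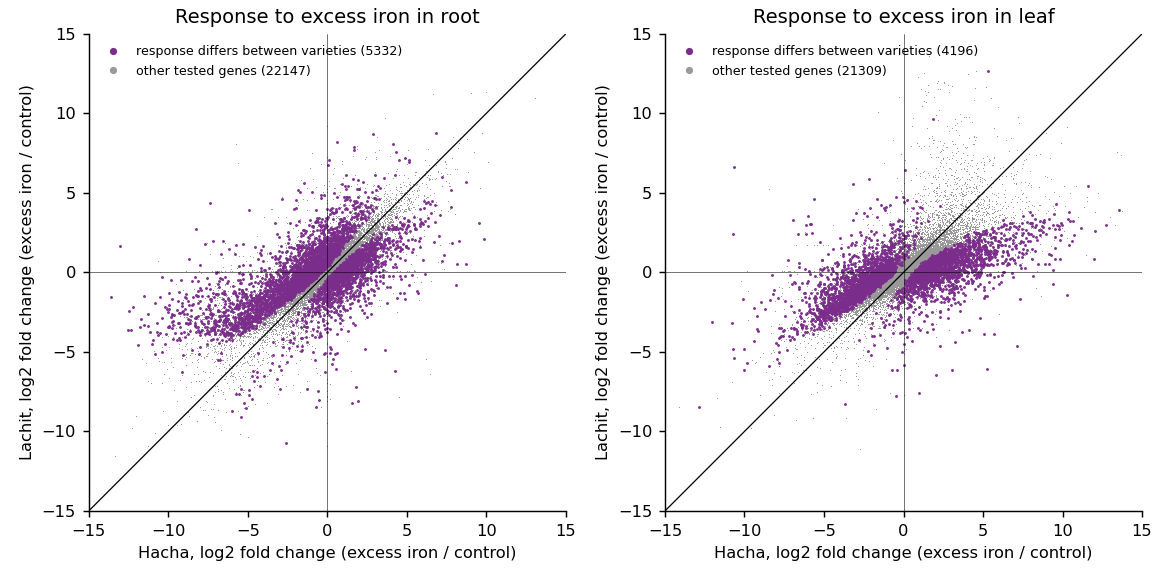
Log2 fold change under excess iron in Hacha (x axis) and Lachit (y axis) for each tested gene in root (left) and leaf (right), with the line of equal response; purple points are the 5332 and 4196 genes whose response differed between the varieties. Most genes lie along one diagonal, at r = 0.76 in root and 0.7 in leaf, with Lachit values nearer to 0.

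In leaves of Hacha, excess iron changed 16664 of the 25505 tested genes, 8262 upward and 8402 downward. Of these, 1983 genes rose and 1971 fell at least 8-fold. OS01G0647200 on chromosome 1, one of the abundant transcripts of control leaves, fell from 3880 ± 560 CPM (SD, n = 3) to 0.494 ± 0.77 CPM (n = 3), a log2 fold change of -12.88 (SE 1.14, adjusted p = 1.23e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), below the controls in all 3 libraries. OS04G0578600 on chromosome 4 fell from 85.9 ± 11 CPM to no reads, at least 1900-fold lower. OS12G0240900 went from 1 read to 16067, a ratio of 17400 with a counting interval of 3130 to 688000 that leaves out the spread between libraries, which had 10562, 3001 and 2504 of these reads (240 ± 200 CPM). OS01G0561600 went from no reads to 65.3 ± 69 CPM, at least 1610-fold higher, with 3092, 1302 and 68 reads in the 3 excess-iron libraries. The adjusted p of these 4 genes lay between 1.13e-05 and 0.00236 in that test.

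In leaves of Lachit, excess iron changed 9883 genes, 5016 upward and 4867 downward. Rises of at least 8-fold were more frequent than falls of that size, with 932 against 481 genes. OS01G0647200 fell in Lachit leaves as well, from 2000 ± 290 to 5.7 ± 1.1 CPM (SD, n = 3 each), and OS04G0578600 from 75.1 ± 20 to 0.193 ± 0.21 CPM, a log2 fold change of -8.51 (SE 0.65, adjusted p = 0.000111, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), lower in all 3 libraries. OS10G0195250 on chromosome 10 fell from 11.3 ± 5.8 CPM to no reads, at least 359-fold lower. OS11G0451700 rose from 0.0561 ± 0.068 to 789 ± 730 CPM and OS03G0133100 from no reads to 59.7 ± 55 CPM, at least 1300-fold higher, but both differed widely between replicates: OS03G0133100 had 2160, 2629 and 16 reads in the excess-iron libraries, and its adjusted p of 0.0356 in the edgeR quasi-likelihood test rose to between 0.0672 and 0.0866 when any 1 of 5 Lachit libraries was left out. The number of called genes was 6450 without Lachit control library 2 and 6142 without control library 3. On log2(TPM + 1), limma called 7397 genes higher and 3508 lower.

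The leaf responses also ran in parallel. Of 8280 genes called in both varieties, 4037 rose in both and 4062 fell in both, against 1625 and 1603 for independent lists, and 181 moved in opposite directions, against 3229. The median ratio of the Lachit to the Hacha log2 fold change was 0.67 (jackknife SE 0.12 over libraries) for the 8099 genes that moved the same way, and 80.1% of them changed more in Hacha. The response differed between the varieties for 4196 genes, 2166 with a higher and 2030 with a lower log2 fold change in Lachit. Of these, 1528 changed in the same direction and more in Hacha, 39 in the same direction and more in Lachit, and 181 in opposite directions. A further 1214 rose and 937 fell past the threshold in Hacha alone, and 130 rose and 150 fell in Lachit alone. Among single genes, OS05G0579600 on chromosome 5 fell from 20.1 ± 2.7 CPM to no reads in Hacha and from 10.2 ± 3.1 to 1.14 ± 0.25 CPM in Lachit, and OS05G0215033 fell from 55.8 ± 15 to 1.12 ± 0.99 CPM in Hacha while Lachit leaves had at most 11 reads of it in a group. OS05G0166600 rose from 0.104 ± 0.18 to 14.4 ± 9.6 CPM and OS07G0663750 from 0.363 ± 0.053 to 13.8 ± 6.5 CPM in Hacha, and both had no reads in excess-iron leaves of Lachit. The control leaves of Lachit held 9 and 23 reads of them over the group, too few to measure a fall there. The count of genes with a differing leaf response ranged from 1244 without Hacha control library 2 to 6665 without Lachit excess-iron library 2. It was 6406 with DESeq2 and 8133 when both tissues shared a fit. On log2(TPM + 1), limma called 4033 higher and 1745 lower in Lachit.

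Placing each library on the axis of the other variety's response gave a score of 0 for a typical control and about 1 for a response of the same size. The log2 CPM of the libraries were offset by 1 count, which draws changes of genes with few reads toward 0. A response of the same size can therefore score below 1. The varieties are scored on different axes, and genes chosen by their calls in one variety tend to change less in the other, so the scores compare libraries within a variety and organ only. Excess-iron roots of Hacha scored 0.9 in both libraries, and those of Lachit 0.55, 0.55 and 0.61. Excess-iron leaves of Hacha scored 0.97 or more in all 3 libraries, and those of Lachit 0.46, 0.59 and 0.26. Each control is scored against the mean of the other controls of its group, so the scores of a control group sum to 0. Control leaves of Lachit scored between -0.02 and 0.02, whereas control library 1 of Hacha leaf scored 0.38 and so stood toward the excess-iron side of the other 2.

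**Figure D2:**
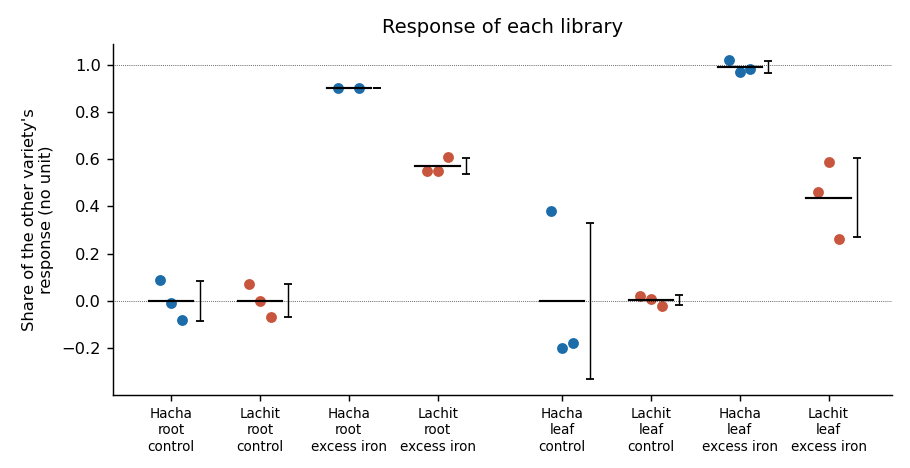
Score of each library on the axis of the other variety's response to excess iron (y axis, no unit), by group (x axis). A score of 0 is the mean of the other control libraries. A response of the same size as in the other variety scores about 1, or less through genes with few reads. Points are libraries, horizontal lines means, and the bars beside them the SD of 2 or 3 libraries. The varieties are scored on different axes. In excess-iron leaves of Lachit the libraries score 0.46, 0.59 and 0.26, and control library 1 of Hacha leaf scores 0.38.

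Roots and leaves shared part of their response. In Hacha, 10284 genes were called in both organs and 74.9% of them moved the same way, and in Lachit 5853 genes with 75.8%. In Hacha, 4424 genes rose in both organs, against 2563 for independent lists, and 3275 fell in both, against 2348. In Lachit the counts were 2833 against 1517 and 1606 against 1173. Over the 24056 genes tested in both organs, 2097 rose in all 4 treatment comparisons, against 162 for independent lists, and 1039 fell in all 4, against 115. These expected numbers take all 4 lists as independent, although the varieties agreed within each organ. The excess over them therefore includes that agreement and does not measure how far the organs shared their response. Of the genes tested in both organs, 2217 were called in no comparison.

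In control roots, the varieties differed in 8148 genes, of which 3982 were higher in Lachit and 4166 higher in Hacha. In 719 genes Lachit was at least 8-fold higher and in 818 Hacha was. In this and the other comparisons of the varieties, sequence differences from the reference change how many reads can be matched. A gene without reads in 1 variety may reflect this, which was not tested. OS02G0600033 on chromosome 2 had 16 ± 2.7 CPM (SD, n = 3) in Lachit and no read in Hacha, at least 412-fold higher in Lachit, and remained without reads in excess-iron roots of Hacha. OS01G0124700 had 14.1 ± 3.6 CPM in Lachit and no read in Hacha, at least 365-fold higher. OS01G0945600 was at least 630-fold and OS03G0846200 at least 599-fold lower in Lachit, where neither had a read, against 24.2 ± 7.4 and 22.8 ± 1.3 CPM in Hacha. In control leaves, OS01G0124700 had 59, 346 and 342 reads in Hacha, and OS01G0945600 had 396, 207 and 104 in Lachit. Reads of these genes could thus be matched in the variety that lacked them in root. OS02G0600033 in Hacha and OS03G0846200 in Lachit had at most 2 reads in any control leaf library. The adjusted p of these 4 genes in control root lay between 2.46e-07 and 8.33e-07 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. By the rule for naming genes, no control root library of one variety overlapped the other. On log2(TPM + 1), limma called 2916 genes higher and 5597 lower in Lachit. With a minimum of 1 on the log2 scale, 4314 genes were called.

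In control leaves, 4857 genes differed, 2652 higher and 2205 lower in Lachit. OS08G0205125 on chromosome 8 had 27 ± 1.8 CPM (SD, n = 3) in Lachit and no read in Hacha, at least 657-fold higher, and OS04G0184100 was at least 464-fold higher. OS05G0215033 was at least 1430-fold lower in Lachit, with no read against 55.8 ± 15 CPM, and OS12G0466200 at least 767-fold lower, with no read against 30 ± 4.3 CPM. Of the 2512 genes that differed in both control organs, 87.7% did so in the same direction, 1125 higher in Lachit in both, against 349 for independent lists, and 1079 lower in both, against 315. The count was 9302 with the control leaves fitted alone, 3224 without Lachit library 1 and 3193 without Lachit library 2.

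Under excess iron the varieties differed in 12846 genes in root, 7312 higher and 5534 lower in Lachit. OS02G0129000 on chromosome 2 had 37.4 ± 10 CPM (SD, n = 3) in Lachit and no read in Hacha, at least 445-fold higher, and OS11G0484450 was at least 353-fold higher. OS03G0575500 had 24.1 ± 7.4 CPM (n = 2) in Hacha and no read in Lachit, at least 616-fold lower, and OS12G0103580 was at least 433-fold lower, from 16.1 ± 2.4 CPM. With a minimum of 1 on the log2 scale, 6921 genes were called.

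In excess-iron leaves, 10864 genes differed, 5734 higher and 5130 lower in Lachit. OS04G0368300 on chromosome 4 had 15.6 ± 4 CPM (SD, n = 3) in Lachit and no read in Hacha, at least 362-fold higher, and OS09G0536350 was at least 286-fold higher, from 14.2 ± 10 CPM. OS07G0131500 had 27.3 ± 11 CPM in Hacha and no read in Lachit, at least 826-fold lower. OS04G0688500 was at least 1320-fold lower in Lachit, but 2626 of its 2857 reads in Hacha came from library 1. With only these 2 groups in the fit, 5015 genes were called, fewer than the 9302 of the control leaves fitted alone. The counts therefore do not settle in which solution the leaves of the varieties differed in more genes. On log2(TPM + 1), limma called 8539 genes higher and 3407 lower in Lachit.

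Leaf-preferred and root-preferred genes were compared between the treatments as groups. A gene was called preferred in an organ when its level in control libraries of the other variety was at least 10 CPM there and at least 8-fold above the other organ, a definition chosen after the data were seen. Because it uses control levels alone, it favours falls in the preferred organ and rises in the other. Leaf-preferred genes took 48.2% ± 4.1 (SD, n = 3) of the reads in control leaves of Hacha and 11.8% ± 1.8 (n = 3) under excess iron, and 47.2% ± 1.7 and 22.8% ± 4.5 (n = 3 each) in Lachit. Of 2008 such genes tested in Hacha leaf, 1504 fell and 213 rose, with a median log2 fold change of -2.44, and of 2078 tested in Lachit leaf, 1437 fell and 149 rose, with a median of -1.5. Of all tested genes, 32.9% fell in Hacha leaf and 19.1% in Lachit leaf, against 74.9% and 69.2% of these leaf-preferred genes. Root-preferred genes fell in roots: 1024 of 1496 fell and 260 rose in Hacha, with a median of -1.85, and 912 of 1435 fell and 314 rose in Lachit, with a median of -1.25. Of all tested genes, 32.7% fell in Hacha root and 29.3% in Lachit root, against 68.4% and 63.6% of these root-preferred genes. Limma's camera with a preset correlation of 0.01 gave Benjamini-Hochberg adjusted p = 7.05e-24 and 4.74e-31 for the leaf-preferred genes in leaves of Hacha and Lachit, and 3.1e-14 and 4.44e-11 for the root-preferred genes in roots. With an estimated correlation none of these calls held (limma camera, Benjamini-Hochberg adjusted p = 0.165, 0.163, 0.078 and 0.078 with an estimated correlation).

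**Figure D3:**
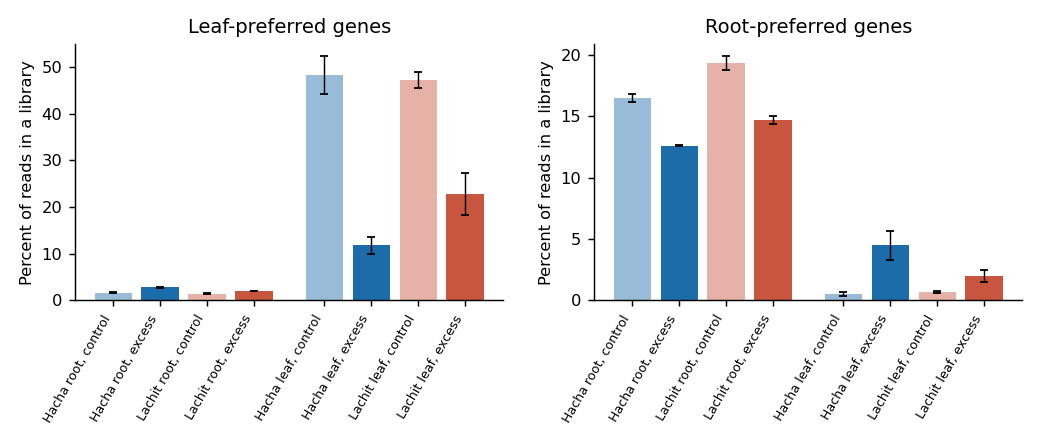
Percent of the reads in a library (y axis) from leaf-preferred (left) and root-preferred genes (right) in each group (x axis); bars are means of 2 or 3 libraries, error bars their SD, pale bars control and full bars excess iron. Leaf-preferred genes took 48.2% of the reads in control leaves of Hacha and 11.8% under excess iron, and 47.2% and 22.8% in those of Lachit.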

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

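The check of the library labels below was chosen after the correlations between libraries were seen. The response to excess iron differed between Hacha and Lachit for 5332 genes in root and 4196 in leaf by the test of the difference of the responses. In root the genes with the largest differences had Benjamini-Hochberg adjusted p-values in the edgeR quasi-likelihood test of 0.000485 (OS05G0215066, expressed in control roots of Hacha and nearly absent from Lachit), 0.000294 (OS11G0484450), 0.000339 (OS11G0183150) and 0.00662 (OS12G0207600). In leaf they had adjusted p-values in that edgeR test of 0.0129 (OS05G0215033), 0.00164 (OS05G0579600), 0.0273 (OS05G0166600) and 0.0099 (OS07G0663750). In that test, with Benjamini-Hochberg adjustment, 4 of these calls were lost in some alternatives. OS11G0484450 and OS12G0207600 had adjusted p = 0.0703 and 0.158 in edgeR with both tissues in one fit (Benjamini-Hochberg). OS05G0215033 lost the call in 2 of 19 alternatives (adjusted p up to 0.0565, edgeR quasi-likelihood test, Benjamini-Hochberg). OS05G0166600 lost it in 4 of 19 (adjusted p up to 1 in that edgeR test, Benjamini-Hochberg), the highest without Lachit control library 2, which held all 9 reads of this gene in Lachit leaves. In 2 of these genes, OS05G0215066 and OS05G0215033, Lachit had almost no reads in either solution, so the difference of responses repeats the difference between the varieties in control plants.

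Of 200 possible splits of the leaf libraries into varieties within each solution, 100 were drawn, and 2 called as many genes as the real labels. The other one called 9415 genes against the real 4196. It exchanged the varieties in the excess-iron solution alone, so that it contrasts the varieties averaged over both solutions and reflects their large difference in expression. All further splits put both varieties into at least 1 group, which adds that difference to the spread between replicates. They called a median of 0 genes and at most 1018, and for that reason the count leaves open whether chance can be excluded. A first draw of 40 of these splits had also held 2. For the difference in root no splits were counted, since excess-iron root of Hacha had 2 libraries.

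The response of Lachit leaf was smaller than that of Hacha leaf, with a median ratio of 0.67 over genes called in both. A candidate explanation is 1 weakly responding library, since excess-iron library 3 of Lachit scored 0.26 on the axis of the Hacha response, against 0.46 and 0.59 for the others. Without it the ratio was 0.75, still below the bound of 0.9 set before this value was seen, which argues against that library as the whole cause. With library totals in place of TMM the ratio was 0.73, and without Hacha control library 1 it was 0.62. Iron uptake and the timing of the response in the 2 varieties, for which these libraries hold no measurement, remain open as biological explanations.

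Library 3 of Lachit excess-iron leaf itself stood nearer to the Lachit control leaves than its replicates did. If RNA of control leaves had been mixed in, the 605 genes that rose at least 8-fold in the other replicates, which reached 13.3% of that level here, would need a control share of 86.7%. The 286 genes that fell at least 8-fold kept a median of 14.5% of their control level, and 80.8% of them lay below 25% of the level that share would bring, where under 5% had been predicted of a mixture, which argues against mixing. A control library under a wrong label is argued against by its highest correlation with a control, 0.926, which lay below the lowest among the controls, 0.98, although its correlation was 0.942 with excess-iron library 1 and only 0.902 with library 2, lower than with any control of Lachit. A plant that responded later or less may account for this library, and the labels give no value to test it.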

How the results depend on the processing

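The 10 counts of called genes were recomputed in 144 alternatives, of which 120 stayed within 1.5 times the reported count and 24 did not. This rule used the total count alone and not its split into rises and falls. That split depended on the processing. On log2(TPM + 1), limma called mostly falls in Hacha root and mostly rises in Lachit leaf. These TPM values had no TMM scaling. With library totals alone in edgeR, the median log2 fold change was -0.31 in Hacha root and 0.29 in Lachit leaf, in the same directions. How much of the shift in calls the missing scaling explains was not tested. The main test called 8145 rises and 8983 falls in Hacha root, and 5016 and 4867 in Lachit leaf. A minimum log2 fold change of 1, which by construction calls fewer genes, gave 10851 in Hacha root, 9049 in Lachit root, 3515 for the difference of root responses, 4314 between varieties in control root and 6921 in excess-iron root. For the other changes the cause was not tested. With DESeq2 the difference of leaf responses called 6406 genes. With both tissues in one fit, the differences of responses called 2057 genes in root and 8133 in leaf. With only the groups compared in the fit, control leaves gave 9302 and excess-iron leaves 5015. This reverses the order of the main counts, 4857 in control and 10864 in excess-iron leaves. Which solution shows more differing leaf genes therefore depends on the fit.

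Leaving out 1 library in turn gave 2801 to 5281 genes for the difference of root responses, with 3434 and 2801 without Hacha excess-iron libraries 1 and 2. For the difference of leaf responses it gave 1244 to 6665: 1911, 6665 and 2692 without Lachit excess-iron libraries 1, 2 and 3, 1244 and 1701 without Hacha control libraries 2 and 3, and 1417, 1611 and 1795 without Lachit control libraries 1, 2 and 3. Lachit leaf gave 6142 to 12070 (6450 and 6142 without control libraries 2 and 3), and control leaves 3193 to 4089 (3224 and 3193 without Lachit libraries 1 and 2). The other counts stayed within 1.5 times. Without the 2 leaf libraries that stood apart, chosen after seeing the data, all 5 leaf counts did so as well. No paired analysis was possible because the labels give each library a running number of its own. The 4 planned list tests were not run, for want of gene names.

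The 40 values of named genes kept their direction in all 536 alternatives, and 13 of these, in 5 values, lost the call. They were OS03G0133100 in Lachit leaf (5 alternatives), OS05G0166600 (4) and OS05G0215033 (2) for the difference of leaf responses, and OS11G0484450 and OS12G0207600 (1 each) for that of root responses. At these depths and this spread, 2% of simulated 2-fold differences of leaf responses were recovered.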

Other observations

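The comparison of neighbouring genes with as many excess-iron genes, below, and the gene groups by organ were chosen after the data were seen. As the gene groups were chosen for low control levels in the other organ, rises there were favoured by the choice. Root-preferred genes, few in control leaves, took a larger share of the leaf reads under excess iron: 0.525% ± 0.17 (SD, n = 3) in control and 4.47% ± 1.2 (n = 3) in excess-iron leaves of Hacha, and 0.674% ± 0.059 and 1.99% ± 0.5 (n = 3 each) in Lachit. Of 1110 such genes tested in Hacha leaf, 449 rose and 254 fell, with a median log2 fold change of 0.47, and of 1118 in Lachit leaf, 263 rose and 169 fell, with a median of 0.27. In Hacha leaf 40.5% of these genes rose and 22.9% fell, against 32.4% and 32.9% of all tested genes. In Lachit leaf the shares were 23.5% and 15.1%, against 19.7% and 19.1%. Limma's camera with the preset correlation gave Benjamini-Hochberg adjusted p = 0.038 and 0.133, and with an estimated correlation adjusted p = 0.251 and 0.375 in Hacha and Lachit. In roots, leaf-preferred genes rose more often than they fell, 612 against 351 of 1809 in Hacha and 635 against 323 of 1890 in Lachit, with medians of 0.26 and 0.17. The share that rose was near that of all tested genes, 33.8% against 29.6% in Hacha and 33.6% against 29.4% in Lachit. The groups differed more in falls, 19.4% against 32.7% in Hacha and 17.1% against 29.3% in Lachit. The limma camera adjusted p of these leaf-preferred genes was 0.0123 and 0.038 with the preset correlation, and adjusted p = 0.197 and 0.212 with an estimated correlation.

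Control library 1 of Hacha leaf scored 0.38 on the axis of the Lachit leaf response, relative to the mean of the other 2 controls. OS03G0133100, which reached 1159 to 4743 reads in excess-iron leaves of Hacha, had 989 reads in this control library and 0 and 1 in the others. Log2 fold changes fell with transcript length, with a Spearman rho across genes of -0.05 to -0.1 in the 4 treatment comparisons. Between the shortest and the longest 25% of genes the median log2 fold change went from 0.21 to -0.35 in Hacha leaf, 0.1 to -0.13 in Lachit leaf, 0 to -0.13 in Hacha root and 0.07 to -0.11 in Lachit root.

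Genes that differed between the varieties in control root lay in blocks along the chromosomes: in windows of 100 tested genes the share that differed ran from 12% on chromosome 2 to 63% on chromosome 9, with an SD of 8.4 points over 270 windows against 4.6 for independent genes, and chromosome 11 had the highest mean share, at 39.5%. Among genes 20 to 50 positions apart, pairs called in the same direction were 1.039 times as frequent as after permutation, above the highest of 1000 permutations at 1.015, which argues against reads shared between near-identical neighbours as the whole cause, although adjacent genes had the highest ratio, 1.59. Genes called for excess iron clustered as well, with window SDs of 6.6 points in Hacha root against 4.8 for independent genes and 6.3 against 4.9 in Lachit root, ratios at that distance of 1.006 in Hacha root, 1.009 in Lachit root and Hacha leaf and 1.014 in Lachit leaf, the last 3 above every permutation, and ratios of 1.22 to 1.43 for adjacent genes. Clustering of changed genes of any kind is argued against as the whole cause only, since the ratio in Hacha root lay below 1.039 by more than the spread of the permutations (SD 0.002 and 0.005), also with as many genes as differ between the varieties (1.008). Blocks of differing ancestry of the 2 varieties are a candidate explanation, and sequence differences from the reference, which change how many reads can be matched, may give the same picture and were not tested.

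For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Every split but the real one also put libraries of both real groups into each group, which adds their difference to the spread between replicates. That mixing lowers the calls, so the counts below leave open whether chance can be excluded. The real labels were the 1 split that called as many genes in Lachit root (16127), Hacha leaf (16664), Lachit leaf (9883), control root (8148), control leaf (4857) and excess-iron leaf (10864) between the varieties, and the highest of the other splits called 0 genes in each.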
